A study of Mus musculus with 18 samples.

How the data were processed

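RNA sequencing was done on 18 mouse liver libraries in 5 groups, untreated WT (3), untreated LKO (3), DEN WT nontumour (6), DEN LKO nontumour (3) and DEN LKO tumour (3), as given by the labels. Per the labels' protocols RNA was extracted with TRIzol and libraries were made with a TruSeq kit. The values are TPM, deposited by the authors as 1 gene table; per the submitters' processing notes fastp, HISAT, RSEM and the mm10 genome were used, and their versions, roles and settings are not given in the sources used here. Each library summed to between 999999 and 1000001 TPM. TPM divides reads by gene length and by the library's total, so a few abundant transcripts lower all others in a library, and counts and depth cannot be recovered. No interval or detection limit that needs counts was therefore computed, and the precision of a single value is unknown. The table also held group means by the authors, which matched the means of the library columns within 3.3e-05 TPM and were not used, and 0 other columns per sample.

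The table had 58126 genes, 55487 of them with a symbol. In all, 55141 of their identifiers (94.9%) were in the GENCODE M21 annotation of mm10, which gave coordinates. Values were taken as log2(TPM + 1). Genes at 1 TPM or more in at least 3 of the 18 libraries were tested, 13872 genes of 29866 above 0 in any library. Limma 3.58.1 in R 4.3.3 fitted all 18 libraries in 1 model of 5 group means with 13 residual degrees of freedom and an intensity trend in the variance. Each of 6 contrasts between groups, and the difference between the genotype effects with and without DEN, was tested 2-sided and adjusted on its own by the Benjamini-Hochberg method, and a gene passed at an adjusted p under 0.05. Figures and library checks were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

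Gene lists were tested as groups with camera from limma, which compares a list with all other genes, at a preset correlation of 0.01 between genes and again with the correlation estimated from the data, and with fry, which tests a list without reference to other genes. The 48 lists of pathways, cell types and sample checks, of which 969 of 976 gene entries were matched, were fixed with the comparisons, tests, filters, the rule for named genes and most alternatives before the data were examined. The 46 lists with 3 or more tested genes entered, and 312 KEGG pathways of 10 to 300 tested genes, from the table's own annotation, were tested with camera the same way. Relative medians are a list's median log2 fold change minus that of all tested genes. The rule named, per comparison, up to 6 genes with the largest rises and up to 6 with the largest falls among genes that passed, had a regular symbol, a mean of 5 TPM or more in the higher group and no overlap between the groups' libraries; 18 genes, among them Ftcd, Pparg, Srebf2, Cidec and Afp, were named whatever their result, and up to 4 members per list discussed. Of the 18, Mki67 was at 0.02 to 2.4 TPM and was removed by the filter, 1 is not reported here, and 0 of the remaining genes passed limma in any comparison.

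Ftcd was tested between genotypes with exact permutation tests within untreated and within DEN nontumour liver. Libraries were called XX or XY from Xist and the Y-linked genes. Pearson correlations between libraries lay between 0.716 and 0.96, and 0 pairs of libraries held identical values. Replicate numbers recur between groups without an explanation in the labels, so libraries of the same number were checked for deviating together from their group means. Between LKO tumour and DEN WT the correlations were 0.56, 0.11 and 0.52 for numbers 1 to 3. All 3 were over 0.1, so these numbers were counted as pairs, from the expression values and not from the labels. Correlations of similar size occurred between groups not counted as pairs. They were 0.58 for number 3 of DEN WT and untreated LKO, and -0.57 and -0.56 for numbers 1 and 3 of DEN WT and untreated WT. On the first principal component, number 1 of LKO tumour and DEN WT scored -89.26 and -89.34, and number 3 scored 69.58 and 86.36. Their deviations can therefore go together without any pairing. Same-numbered LKO nontumour and tumour libraries correlated at 0.35, 0.3 and -0.03 and were not counted, although they were of the same sex. The pairs are thus an assumption, and a shared animal or batch is not shown. A fit with the replicate number as a block was made for every comparison as an alternative, and for LKO tumour against DEN WT it called 0 genes, where the fit without the block called 69. The blocked fit held the compared groups alone, while the 69 came from the fit of all 18 libraries. Without the block, a fit of the compared groups alone already lost 9 of the 12 genes named for this comparison. The fall to 0 is therefore not due to the block alone.

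The fit was tested on simulated data with each gene's mean and residual spread in these libraries, with 50 genes changed at each of 4 sizes among 13872. For untreated LKO minus untreated WT, 4%, 26%, 74% and 84% of genes changed by 1, 2, 3 and 4 on the log2 scale were called, with 6 unchanged genes among 100 calls. For LKO tumour minus DEN WT, the shares were 4%, 52%, 80% and 88%, with 12 unchanged genes among 124 calls. Camera called 0 of 46 lists without a simulated change and the changed list of 25 genes in both comparisons. The simulated genes were independent of one another, so this does not test camera's preset correlation of 0.01. The estimates for the lists in these libraries were 0.268 to 0.821. Variation that many genes share across libraries was also absent, while in the real data the first principal component held 42.6% of the variance. Another division of the real LKO tumour and DEN WT libraries called 5708 genes. The simulated shares and false calls of limma therefore need not hold in these data. A pseudocount of 0.1, no filter or a mean of 5 TPM or more, median-ratio and quantile scaling, a fit of the compared groups alone, array weights, a variance without trend, a fold threshold, the replicate block and leaving out each library were tried as alternatives. A term for XX or XY, the mitochondrial share as a covariate, removal of mitochondrial and 5S ribosomal RNA genes, and leaving out the 3 libraries labelled WT with Ftcd under 5 TPM were added after seeing the data. The term for XX or XY rests on replicate 1 of DEN LKO nontumour and of tumour, the only XX libraries labelled LKO. Their mitochondrial shares were 36.16% and 30.79%, against 10.41% to 18.7% in the XY DEN LKO libraries. This term therefore cannot part sex from that share. Isoforms, variants and alternative splicing were not analysed here, since the table holds gene values alone.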

Results

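RNA sequencing of mouse liver gave 18 libraries in 5 groups. The mice carried a liver-specific knockout of Ftcd (LKO) or were labelled wild type (WT). Ftcd encodes the enzyme that passes the formimino group of histidine breakdown to tetrahydrofolate. Livers were either untreated (3 libraries labelled WT, 3 labelled LKO) or came from mice given diethylnitrosamine (DEN), a liver carcinogen that hepatocytes activate to a DNA-alkylating form. DEN was injected at 20 mg/kg on postnatal day 14 and tissue was taken 12 months later. Untreated mice were 12 months old, about 14 days younger. The DEN groups were nontumour liver labelled WT (6 libraries), nontumour liver labelled LKO (3) and tumour labelled LKO (3). Each library was given as TPM, a length-corrected share of transcripts. TPM values sum to 1000000 per library (within rounding) and keep no sequencing depth, so the depth behind each value is unknown. No label says that the replicates of a group are separate animals. If they are not, the p-values measure only the spread between these samples, which may be technical.

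Ftcd (ENSMUSG00000001155, mm10 chromosome 10, 76575648 to 76590338, plus strand) lay between 0.1 and 3.16 TPM in all 9 libraries labelled LKO. Of the 9 libraries labelled WT, 6 had 61.17 to 106.1 TPM. By contrast, DEN WT 1 had 2.36 TPM, DEN WT 2 had 2.5 TPM and untreated WT 3 had 1.77 TPM, inside the range of the LKO labels. Group means were 45.93 ± 38.85 TPM (SD, n = 3) in untreated WT and 2.4 ± 0.71 (n = 3) in untreated LKO. After DEN they were 52.67 ± 41.88 (n = 6) in DEN WT nontumour, 0.73 ± 0.35 (n = 3) in DEN LKO nontumour and 0.67 ± 0.94 (n = 3) in DEN LKO tumour. On log2(TPM + 1), LKO minus WT was -4.00 in DEN nontumour liver (2-sided exact permutation p = 0.0238). It was -2.81 in untreated liver (exact permutation p = 0.3, where 3 against 3 allows 0.1 at the least). In limma, Ftcd did not pass after adjustment over all genes in either comparison (adjusted p = 0.252 and 0.831). All directions below therefore compare libraries as labelled, with these 3 libraries kept in the WT groups.

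**Figure D1:**
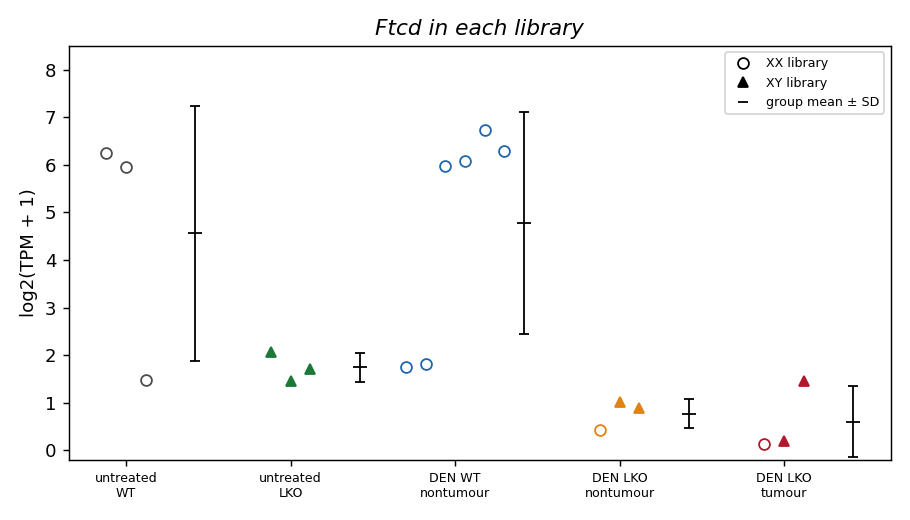
Ftcd in each library on a log2(TPM + 1) axis, by group; open circles mark XX and triangles XY libraries, and dashes with bars give the group mean ± SD. All 9 libraries labelled LKO lie at 3.16 TPM or below, as do 3 of the 9 labelled WT.

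Transcripts of the sex chromosomes differed between the labels. Xist (ENSMUSG00000086503, mm10 chromosome X, 103460366 to 103483254), the noncoding RNA of the inactive X, was present in all 9 libraries labelled WT, with Y-linked genes summing to at most 0.13 TPM, so these libraries were XX. The 3 untreated LKO libraries had Y-linked sums of 16.39 to 17.77 TPM and were XY, as were replicates 2 and 3 of DEN LKO nontumour and of DEN LKO tumour. Replicate 1 of both was XX with Xist at 55.09 and 35.39 TPM. Sex and genotype label were thus the same division in untreated liver and nearly so after DEN. The share of TPM from mitochondrially encoded genes also varied, from 4.2% to 38.31%. Its means were 12.21% ± 9.49 (SD, n = 3) in untreated WT and 22.75% ± 6.61 (n = 3) in untreated LKO. After DEN they were 11.75% ± 13.13 (n = 6) in DEN WT nontumour, 24.15% ± 10.42 (n = 3) in DEN LKO nontumour and 19.08% ± 10.52 (n = 3) in DEN LKO tumour. Across the 18 libraries the log2 of this share followed the first principal component, which held 42.6% of the variance (Pearson r = -0.877, Spearman rho = -0.884, permutation p = 1e-05 for both, the smallest the permutations can give). The correlation was -0.832 without the 2 farthest libraries, -0.843 for deviations from group means and -0.827 within the 6 DEN WT libraries. The second component, the other of the 2 tested, held 13.5% and showed r = 0.126 (permutation p = 0.622) and rho = 0.152.

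**Figure D2:**
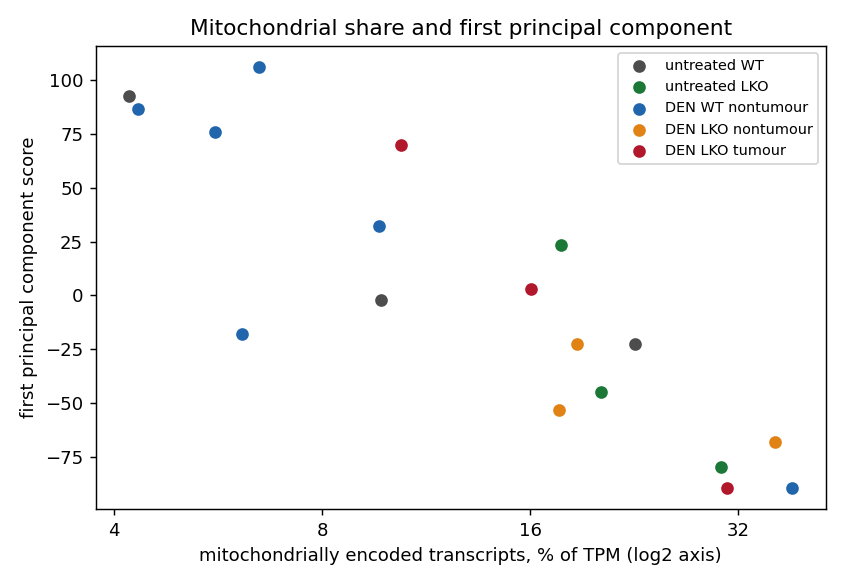
Percent of TPM from mitochondrially encoded genes (log2 axis) against the score of each library on the first principal component (no unit), coloured by group. Libraries with a larger mitochondrial share have lower scores, with Pearson r = -0.877 over 18 libraries.

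The first comparison asks how loss of Ftcd changes untreated liver. Between untreated LKO and the libraries labelled WT, the largest changes were in genes that male and female mouse livers express differently. Of the 28 tested genes of the female-biased list, 18 fell and none rose, and of the 21 of the male-biased list, 8 rose and none fell. Adjusted over the list alone, these counts were 27 and 19. Cyp2a4, a steroid 15-alpha-hydroxylase of female liver, had 0.92 ± 0.75 TPM in untreated LKO and 729.89 ± 241.67 in untreated WT (SD, n = 3 and 3; log2 fold change -8.60 ± 1.03 SE, limma adjusted p = 0.000407). Cyp4a12a, a male-specific fatty acid omega-hydroxylase, had 138.44 ± 28.89 against 0.24 ± 0.17 TPM (6.80 ± 0.81, adjusted p = 0.000407). The 3 LKO livers were XY and the 3 WT livers XX, and 1 Y-linked gene of the 3 tested passed as higher.

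Other genes of male liver that rose were Mup21 (6.42, adjusted p = 0.0218), which encodes a major urinary protein, and the cytochrome P450 gene Cyp2d9 (6.05, adjusted p = 0.00188). So did Hsd3b5 (5.20, adjusted p = 0.00255), a 3-ketosteroid reductase, and the organic anion transporter Slco1a1 (4.46, adjusted p = 0.000748). Cyp4a12b had 28.22 ± 11.79 TPM in untreated LKO (SD, n = 3; adjusted p = 0.0143) and was listed at 0 in untreated WT. The large falls also included Cyp3a41a (-10.89, adjusted p = 0.00644), a female-specific P450 with 0.06 ± 0.10 against 2078.99 ± 757.53 TPM. They also included A1bg (-9.05, adjusted p = 0.000639), a secreted immunoglobulin-domain protein, and Sult2a1 (-8.26, adjusted p = 0.000662), a bile acid and steroid sulfotransferase. Cyp2c69 (-7.69, adjusted p = 0.00226) and Cyp3a41b (-7.59, adjusted p = 0.0212) fell as well. In each of these 12 genes the 3 libraries of one group lay wholly above the 3 of the other. Mup21, Cyp4a12b and Cyp3a41b depended on single libraries, 3 of the 12 genes no longer passing without untreated LKO 1, LKO 3 or WT 2, 2 without WT 1 or WT 3 and 1 without LKO 2. The same 3 did not pass with no filter on low values, at the same fold changes (adjusted p = 0.106, 0.0705 and 0.101), nor Mup21 with a pseudocount of 0.1 (8.35 ± 1.85, adjusted p = 0.0566). With median-ratio scaling or quantile normalization Cyp3a41b did not pass (-7.30 ± 1.65 and -7.29 ± 1.65 against -7.59 ± 1.46, adjusted p = 0.0613 and 0.0657). Values of close paralogs, such as the Mup, Cyp and Sult2a families, are uncertain because reads they share can be split between them. Fold changes are on the log2(TPM + 1) scale, which understates changes in genes of low TPM.

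**Figure D3:**
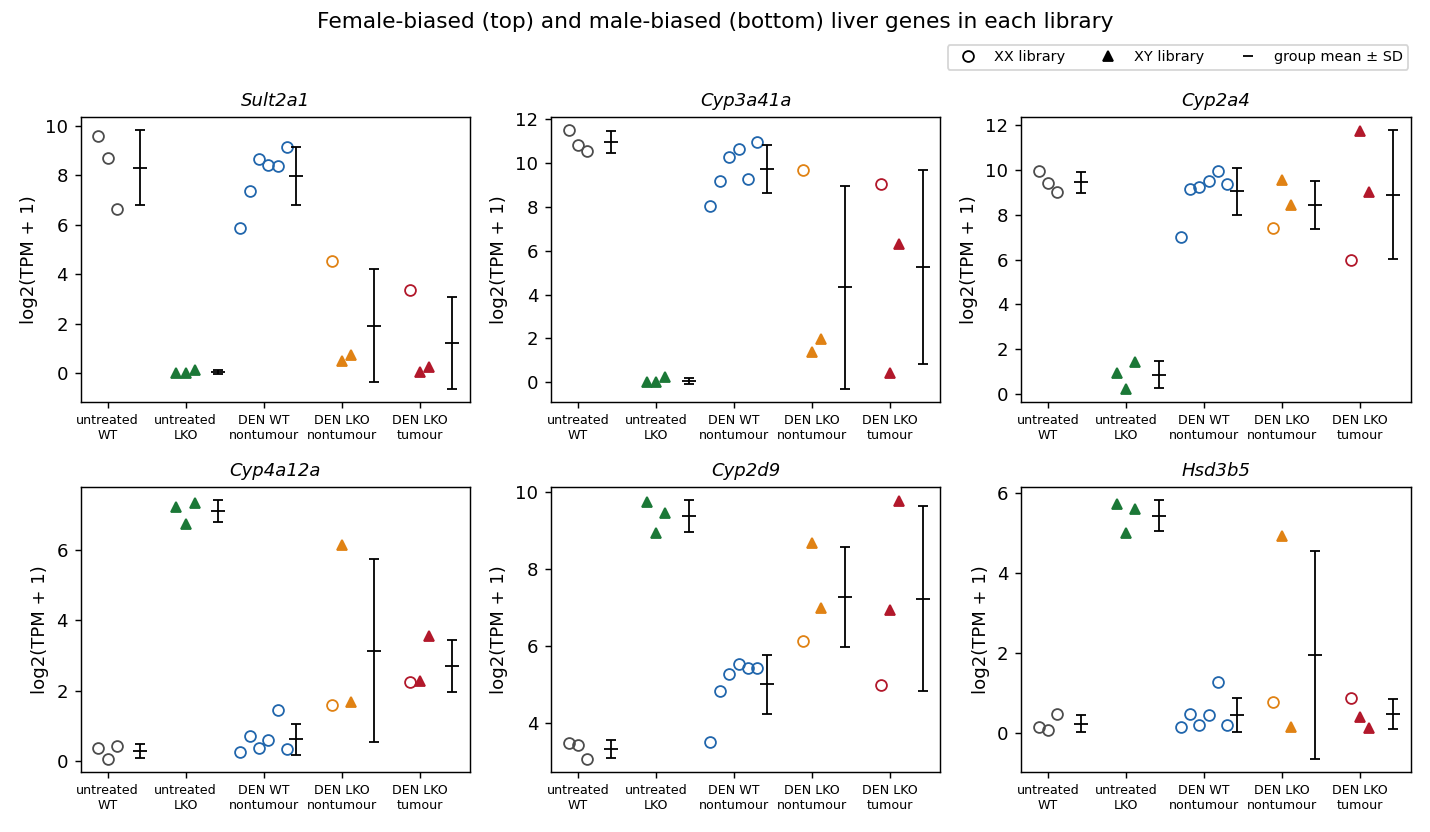
Female-biased genes Sult2a1, Cyp3a41a and Cyp2a4 (top) and male-biased genes Cyp4a12a, Cyp2d9 and Hsd3b5 (bottom) in each library on log2(TPM + 1) axes, by group, with open circles for XX, triangles for XY libraries and dashes with bars for the group mean ± SD. Untreated XX and XY libraries separate in all 6 genes, and Cyp2a4 is high in the XY libraries of the DEN LKO groups (346 to 3428.07 TPM) but not in untreated LKO (0.17 to 1.66 TPM).

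Among the other lists in untreated LKO, the 25 tested genes of cholesterol synthesis, the targets of SREBP2, were all below untreated WT in sign and none passed alone (relative median -0.82, camera adjusted p = 3.72e-06). Its call was lost (adjusted p = 0.948 with an estimated correlation), and its relative median was -0.53 without untreated WT 1. Fatty acid synthesis genes gave -0.83 (camera adjusted p = 0.000582, and adjusted p = 0.948 with an estimated correlation), and -0.45, -0.45 and -1.62 without untreated LKO 1, 2 and 3, the middle one with adjusted p = 0.0775. Macrophage and Kupffer cell genes gave -0.62 (adjusted p = 0.000582, and adjusted p = 0.948 with an estimated correlation), and -0.39 without untreated WT 1 and -0.25 without untreated LKO 3, the latter with adjusted p = 0.194. The 5 tested red cell genes gave 0.78 (adjusted p = 0.00016, and adjusted p = 0.457 with an estimated correlation) and 0.49 without untreated LKO 1, and of these Alas2, the first enzyme of haem synthesis in red cells, rose (3.25 ± 0.59, adjusted p = 0.0137). The lipid droplet genes of PPARg had a median of -0.25 and a mean of 0.14. Camera placed them higher (adjusted p = 0.0262, and adjusted p = 0.948 with an estimated correlation). Without untreated LKO 3, WT 2 or WT 3 the camera adjusted p was 0.4, 0.0591 or 0.127. The list's relative median moved from 0.08 to -0.21 without LKO 3, 0.17 without LKO 1, 0.19 without LKO 2, 0.22 without WT 1 and 0.02 without WT 2 or WT 3. Of these, Cidea, a fat droplet coat protein, had 1.99, 1.23 and 81.23 TPM in untreated LKO 1 to 3 and was listed at 0 in untreated WT. Cidec had 7.15, 5.07 and 67.29 TPM, against a mean of 3.20 ± 0.46 (SD, n = 3) in untreated WT, and neither passed in limma. Fasn (-1.92 ± 1.19), fatty acid synthase, did not pass, nor did Pparg (-0.24 ± 0.61) or Srebf2 (-0.87 ± 0.57).

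These lists moved together with others of hepatocytes and with the mitochondrial share. Hepatocyte identity genes gave -0.54 (camera adjusted p = 0.00305, and adjusted p = 0.948 with an estimated correlation), and -0.33 without untreated WT 2. Heat shock genes gave -0.72 (adjusted p = 0.00298, and adjusted p = 0.948 with an estimated correlation). Genes of hepatocytes around the central vein gave -0.81 (adjusted p = 0.00594, and adjusted p = 0.948 with an estimated correlation), and -0.40, -0.43 and -1.26 without untreated LKO 2, WT 1 and WT 3. Without LKO 2, LKO 3, WT 1 or WT 2 it was not called. Mitochondrially encoded genes lay higher (1.41, adjusted p = 5.43e-10, and adjusted p = 0.363 with an estimated correlation), at 0.77 without untreated WT 1 and 2.14 without untreated WT 3.

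A term for XX or XY and the mitochondrial share as a covariate, both chosen after seeing the data, changed these lists. With the sex term the pericentral list turned to 0.20 (camera adjusted p = 0.194). Cholesterol synthesis (-0.86, adjusted p = 0.14), red cells (0.57, 0.17), PPARg lipid droplet genes (-0.21, 0.607), hepatocyte identity (-0.43, 0.166) and heat shock genes (-1.23, 0.0595) were no longer called. Kupffer cell genes moved to -1.33 and mitochondrially encoded genes to 3.09, both called. With the mitochondrial share the pericentral (-0.24, adjusted p = 0.155), hepatocyte identity (-0.15, 0.471) and heat shock (-0.28, 0.111) lists were no longer called. Cholesterol synthesis then gave -0.37, Kupffer cell genes -0.28 and lipid droplet genes 0.32, all called. Lipid droplet genes were not called with median-ratio scaling (0.18, adjusted p = 0.0857) or quantile normalization (0.16, 0.055).

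Of 13872 genes tested by limma, 60 passed between untreated LKO and untreated WT, 24 higher and 36 lower, and 576 were at an unadjusted p under 0.05. The groups did not overlap in 11.4% of the genes, where chance gives 10%. The median log2 fold change of all genes was -0.33. The female-biased list (relative median -4.76, camera adjusted p = 6.11e-70) and the male-biased list (3.32, adjusted p = 9.44e-70) also passed with the estimated correlation (adjusted p = 0.00131 for both), as did the Y-linked genes (3.01, adjusted p = 0.00557), and no other list did. The count was 34 without untreated LKO 1, 38 without untreated LKO 2, 35 without untreated WT 1, 33 without untreated WT 2 and 59 without the 3 low-Ftcd libraries labelled WT, a choice made after seeing the data. With median-ratio scaling it was 96, of which 58.3% were higher against 40% here. With a term for XX or XY, chosen after seeing the data and resting on the DEN LKO libraries alone to part sex from genotype, 26 genes passed, 9 of them among the 60, and 10 of the 12 genes named above did not, the exceptions being Slco1a1 and Cyp2a4. The fold changes of the 10 were smaller in size. Those of Cyp3a41a (-4.03 ± 1.55 from -10.89 ± 1.85), Cyp3a41b (-2.63 ± 1.43), Mup21 (3.32 ± 1.57), Cyp2d9 (3.51 ± 1.01), Cyp4a12b (2.77 ± 1.13), Sult2a1 (-4.69 ± 1.09) and Cyp2c69 (-4.91 ± 1.45) moved by over 1.5 times. Those of A1bg (-6.18 ± 1.41), Cyp4a12a (5.31 ± 1.11) and Hsd3b5 (4.63 ± 1.17) moved less. The female-biased and Y-linked lists moved to -2.37 and 1.28, both still called.

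The second comparison asks how loss of Ftcd changes nontumour liver after DEN. The sulfotransferase gene Sult2a1 (mm10 chromosome 7, 13796246 to 13837409) had 7.87 ± 12.7 TPM in LKO and 311.6 ± 180.95 in the libraries labelled WT (SD, n = 3 and 6; -6.05 ± 0.94 SE, limma adjusted p = 0.0169). Its neighbours Sult2a2 (-5.50 ± 0.80, adjusted p = 0.0169) and Sult2a5 (-3.37 ± 0.59, adjusted p = 0.0372) fell with it, as did A1bg (-6.61 ± 0.99, adjusted p = 0.0169). All 4 had also fallen in untreated LKO, where 0.01 shared genes would be found by independent draws. Both comparisons set mostly XY libraries labelled LKO against XX libraries labelled WT. The shared genes therefore do not part genotype from sex. Their values in the XX library DEN LKO nontumour 1 (Sult2a1 22.53, A1bg 24.62 TPM) exceeded those of the XY libraries 2 and 3 (Sult2a1 0.4 and 0.67, A1bg 0.24 and 0.44 TPM). Genes of fatty acid oxidation controlled by PPARa lay below the libraries labelled WT as a group, though no member passed over all genes. The list's call was lost (adjusted p = 0.957 with an estimated correlation).

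Of the 28 female-biased genes, 4 fell over all genes and 18 adjusted over the list alone (relative median -2.68, camera adjusted p = 1.02e-16, and adjusted p = 0.397 with an estimated correlation; fry adjusted p = 0.0228). The male-biased list lay higher (1.14, adjusted p = 3.12e-07, not called with an estimated correlation), with 0 members past limma's threshold and 4 over the list alone. Its relative median was 1.79 without DEN LKO nontumour 1 and 0.41 (adjusted p = 0.0592) without DEN LKO nontumour 2. The 27 PPARa targets gave -1.05 (adjusted p = 1.63e-08, and adjusted p = 0.957 with an estimated correlation), with 6 lower when adjusted over the list alone. Among them, Cyp4a14, a fatty acid omega-hydroxylase, had 5.67 ± 4.56 TPM against 178.06 ± 119.21 (SD, n = 3 and 6; -4.56 ± 0.95, limma adjusted p = 0.117, over the list 0.00402), and the peroxisomal thiolase Acaa1b had 95.44 ± 26.79 against 600.24 ± 260.49 TPM. Genes of hepatocytes around the central vein gave -1.06 (adjusted p = 0.000641, and adjusted p = 0.957 with an estimated correlation), with the ethanol-oxidising P450 Cyp2e1 at 484.57 ± 100.36 TPM against 4581.82 ± 2942.09 (limma fold change -2.72, not passed). These hepatocyte lists moved with the mitochondrial share, which averaged 24.15% in DEN LKO nontumour and 11.75% in DEN WT. With that share as a covariate, chosen after seeing the data, the PPARa list gave -0.60 and the pericentral list -0.53, both still called. With a term for XX or XY, also chosen after seeing the data, the PPARa list gave -0.65, the female-biased list -1.33 and the male-biased list 0.75, all called, and the pericentral list -0.11 (adjusted p = 0.687). Cholangiocyte genes lay higher (0.62, camera adjusted p = 0.0156, and adjusted p = 0.957 with an estimated correlation), at 1.10 without DEN LKO nontumour 1. They were not called without DEN LKO nontumour 2 or 3 or DEN WT 1, with a pseudocount of 0.1 (adjusted p = 0.0503) or with the sex term (0.066, adjusted p = 0.84).

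The folate and one-carbon list, the pathway Ftcd feeds, had 32 tested genes with a relative median of -0.50 (camera adjusted p = 0.0172, and adjusted p = 0.957 with an estimated correlation), and without DEN LKO nontumour 2 the adjusted p was 0.0592. It was -0.32 (adjusted p = 0.0611) with quantile normalization, -0.48 (0.106) with a sex term and -0.13 (0.211) with the mitochondrial share as a covariate, the last 2 chosen after seeing the data. None of its members passed. Gnmt, which disposes of excess methyl groups, had 124 ± 104.98 TPM against 1084.27 ± 927.02 (SD, n = 3 and 6; log2 fold change -2.76). The folate enzymes Aldh1l1 and Shmt1 had log2 fold changes of -1.83 and -1.76. The 4 genes of histidine breakdown, Ftcd among them, gave -0.95 (camera adjusted p = 0.0119, not called with an estimated correlation), -0.57 (0.0707) with quantile normalization and -1.29 (0.0765) with the sex term. Genes of fetal liver and liver cancer gave 1.01 (adjusted p = 0.00766, and adjusted p = 0.957 with an estimated correlation), and 0.38 without DEN LKO nontumour 2 (adjusted p = 0.0986). With the sex term their direction turned (-0.064, adjusted p = 0.845). Neither Afp (0.90 ± 0.90) nor Gpc3 (-0.15 ± 0.58), markers of that state, passed. Pparg (-0.62 ± 0.53) and Srebf2 (-0.62 ± 0.50) did not either. Grm8 (mm10 chromosome 6, 27275119 to 28135178), a glutamate receptor gene chosen after its values were seen, rose from 0.04 ± 0.04 TPM in DEN WT to 2.77 ± 0.95 in DEN LKO nontumour (SD, n = 6 and 3; 1.82 ± 0.30, limma adjusted p = 0.022). It had 2.81 ± 1.93 TPM in untreated LKO, but 0.08 ± 0.07 TPM in LKO tumour (n = 3).

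In DEN nontumour liver 8 genes passed, 4 higher and 4 lower, and 1811 were at an unadjusted p under 0.05. The 4 higher were Grm8, the predicted gene Gm3788 (4.17 ± 0.71, adjusted p = 0.0305), also chosen after its values were seen, and 2 assembled loci without an annotated gene. The groups did not overlap in 4.1% of genes (chance 2.38%), and the median of all genes was -0.20. The count was 202 without DEN WT 1, 28 without DEN LKO nontumour 1, 5 without DEN WT 3, and 4 without DEN WT 5. It was 2 without DEN LKO nontumour 3, 1 without DEN LKO nontumour 2 and 0 without DEN WT 6. The 4 named genes that fell did not pass without DEN LKO nontumour 2 or 3 or DEN WT 6, nor 1 of them, Sult2a5, without DEN WT 3, 4 or 5. With median-ratio scaling 72.7% of 11 genes and with quantile normalization 64.3% of 14 were higher, against 50% here. Without the 2 low-Ftcd libraries labelled WT, DEN WT 1 and 2, chosen after seeing the data, 1159 genes passed, 375 higher and 784 lower. This also removes the DEN WT library with the largest mitochondrial share, 38.31%. With the mitochondrial share or the sex as a covariate, also chosen after seeing the data, 0 and 4 genes passed, and 0 of the 4 were among the 8. The 4 named genes that fell did not pass with either covariate or in a fit of the compared groups alone. With the mitochondrial share the fold changes were somewhat smaller and their SE larger, -5.83 ± 1.11 for A1bg (adjusted p = 0.154), -5.55 ± 1.08 for Sult2a1 (0.171), -5.22 ± 0.93 for Sult2a2 (0.135) and -2.94 ± 0.66 for Sult2a5 (0.301). With sex they were smaller, -4.70 ± 1.08, -3.67 ± 0.83, -3.78 ± 0.83 and -2.23 ± 0.64 (adjusted p = 0.178 for each). The sex term rests on the XX libraries of DEN LKO nontumour and tumour, which had the largest mitochondrial share of their groups, so it does not adjust for sex alone. The fit of the compared groups left them unchanged, with 7 instead of 13 residual degrees of freedom (SE 1.02, 0.92, 0.81 and 0.63, adjusted p = 0.0836 for the first 3 and 0.148 for Sult2a5). With a pseudocount of 0.1, all but A1bg did not pass, at larger fold changes and SE (Sult2a1 -6.93 ± 1.23, adjusted p = 0.0726). Sult2a5 was also lost with no filter (adjusted p = 0.0688), a mean of 5 TPM or more (0.0582) and median-ratio scaling (-3.05 ± 0.56, adjusted p = 0.0604). Removal of mitochondrial and 5S genes, chosen after seeing the data, ended its call as well (-3.35 ± 0.60, limma adjusted p = 0.0515).

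Across 13872 genes, which are not independent replicates, the LKO minus WT fold changes of untreated and DEN nontumour liver correlated with Pearson r = 0.519 and Spearman rho = 0.599, and 73.9% had the same sign. These comparisons share no library. In both, however, XY libraries occurred only under the LKO label, and the mean mitochondrial share was higher in LKO. The simulations below hold neither difference, so the correlation does not show a repeated effect of the genotype. Libraries simulated without any difference gave r = 0.042 ± 0.293 (SD), with 3 of 100 as high, and the covariance was 0.296 against 0.022 simulated. The test of the difference between the 2 genotype effects called 0 genes by limma, with 332 at an unadjusted p under 0.05. Thus no single gene was shown to respond to the genotype differently after DEN. It called 10 genes without DEN LKO nontumour 2, 2 without DEN WT 2 and 1 without DEN LKO nontumour 3 or untreated LKO 1. As groups, the male-biased genes differed by -2.12 (camera adjusted p = 3.96e-31, and adjusted p = 0.0839 with an estimated correlation). The female-biased genes differed by 1.93 (adjusted p = 1.26e-19, and adjusted p = 0.207 with an estimated correlation; 1.15 without DEN LKO nontumour 1). The LKO minus WT medians of both were smaller in size after DEN. DEN LKO nontumour 1 was XX, while all untreated LKO libraries were XY, so these differences also hold a change in the mix of sexes.

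The third comparison asks what sets tumours apart from nontumour liver of LKO mice given DEN. Genes of cell division lay higher in tumour as a group, all 22 tested members having a positive fold change, though none passed alone. The call was lost (adjusted p = 0.782 with an estimated correlation), and the relative median was 0.85, or 0.27 without tumour 3. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, had 9.47, 7.75 and 37.15 TPM in tumours 1 to 3 (log2 fold change 1.59), and Birc5, a mitotic survival protein, had 6.44 ± 4.63 TPM in tumour against 1.66 ± 1.1 (SD, n = 3 and 3; 1.40). Lipid droplet genes controlled by PPARg were higher in sign in 17 of 18, with Cidec, which fuses fat droplets, at 57.32 ± 75.15 against 6.96 ± 8.61 TPM (2.53 ± 0.91, limma adjusted p = 0.943). Cidec in single tumours was 17.72, 10.26 and 143.99 TPM. Genes of hepatocytes around the portal vein lay lower as a list, such as Sds, serine dehydratase, at 55.33 ± 36.11 against 182.71 ± 62.98 TPM (-1.85), and Hal, the first enzyme of histidine breakdown (-1.76). Neither gene passed, and the list's call was lost (adjusted p = 0.782 with an estimated correlation).

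The proliferation list had a relative median of 0.85 (camera adjusted p = 1.2e-10, and adjusted p = 0.782 with an estimated correlation) and 5 members past the threshold adjusted over the list alone. It was called whichever single library was left out, with 0.27 without tumour 3. The PPARg lipid droplet list gave 0.78 (adjusted p = 0.00015, and adjusted p = 0.905 with an estimated correlation), with Anxa2 (2.45), the fatty acid binding protein Fabp4 (2.35) and Plin4 (1.21) among its larger fold changes. The list gave 0.23 without tumour 3, still called. The periportal list gave -0.80 (adjusted p = 7.39e-08, and adjusted p = 0.782 with an estimated correlation) and -1.22 without tumour 2. Oxidative stress targets of NRF2 gave 0.53 (adjusted p = 0.00763, and adjusted p = 0.924 with an estimated correlation). The adjusted p was 0.28 without DEN LKO nontumour 1 (relative median 0.22), 0.0657 without tumour 2 (0.28) and 0.0739 without tumour 3. The relative median was 0.80 without tumour 1 or DEN LKO nontumour 3. Male-biased genes gave -0.86 (adjusted p = 1.72e-07, and adjusted p = 0.782 with an estimated correlation), and without DEN LKO nontumour 2 the relative median was -0.31 (adjusted p = 0.638). Pparg (1.03 ± 0.61; 12.05 ± 13.83 against 3.51 ± 1.08 TPM), Srebf2 (0.82 ± 0.57) and Sqle (0.94 ± 0.87) did not pass, and Afp (-0.10 ± 1.04) and Glul (-0.73 ± 0.97) did not.

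Markers of other cell types also lay lower in tumour. Cholangiocyte genes gave -0.57 (camera adjusted p = 0.00807, and adjusted p = 0.905 with an estimated correlation), and stellate cell and fibroblast genes -0.38 (adjusted p = 0.00807, and adjusted p = 0.905 with an estimated correlation). Mitochondrially encoded genes gave -0.73 (adjusted p = 0.00196, and adjusted p = 0.905 with an estimated correlation), and red cell genes -0.73 (adjusted p = 0.0332, and adjusted p = 0.905 with an estimated correlation). All 4 rested on single libraries. The cholangiocyte call ended without tumour 1 or 2 or DEN LKO nontumour 2 or 3 (relative medians -0.61, -0.35, -0.45 and -0.26), and the stellate call without tumour 1 (-0.31) or DEN LKO nontumour 3 (-0.24). The mitochondrial call ended without tumour 3 (-0.16) or DEN LKO nontumour 1 (-0.40) and with quantile normalization (-0.55, adjusted p = 0.117), and gave -1.54 without tumour 1. Red cell genes turned to 0.073 without DEN LKO nontumour 2 and were not called without tumour 1 or 3 or in a fit of the compared groups alone (adjusted p = 0.0551).

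No gene passed between tumour and nontumour liver of LKO mice in limma, the smallest adjusted p being 0.169, with 380 genes at an unadjusted p under 0.05. The groups did not overlap in 3.8% of genes, below the 10% of chance, and the median of all genes was 0.23. Without tumour 1, from the XX libraries, 21 genes passed, 19 higher and 2 lower, and 2, 1 and 1 passed without DEN LKO nontumour 1, 2 or 3.

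The fourth comparison sets LKO tumours against nontumour liver labelled WT, both after DEN. Of the 22 proliferation genes 4 rose, Ube2c (2.39 ± 0.46, 18.12 ± 16.5 against 2.06 ± 1.11 TPM; SD, n = 3 and 6; limma adjusted p = 0.0219), Cdkn3 (2.23, adjusted p = 0.0414), Birc5 (1.71, adjusted p = 0.0463) and Cdc20 (2.02, adjusted p = 0.0463). Adjusted over the list alone, 9 rose. Insyn1 (mm10 chromosome 9, 58488603 to 58499780), which encodes a scaffold of inhibitory synapses, had 23.44 ± 16.62 against 0.33 ± 0.55 TPM (3.85 ± 0.57, adjusted p = 0.00628), with 4.28, 32.15 and 33.9 TPM in the 3 tumours. Of the 28 female-biased genes 11 fell, and 20 adjusted over the list alone.

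Lpl (2.73 ± 0.52, 35.31 ± 23.39 against 3.55 ± 1.49 TPM, adjusted p = 0.0219), lipoprotein lipase, and Slc16a1 (2.52 ± 0.53, adjusted p = 0.0414), the lactate transporter MCT1, rose in tumour. Fkbp11 (2.80 ± 0.53, adjusted p = 0.0219), a prolyl isomerase of the secretory pathway, and Nupr1 (2.91 ± 0.57, adjusted p = 0.0261), a stress-induced chromatin protein, rose too. In DEN LKO nontumour 1 to 3, Fkbp11 had 23.22, 130.5 and 49.03 TPM, Lpl 4.9, 23.22 and 20.58, and Slc16a1 34.49, 67.42 and 42.5. The highest DEN WT values were 20.4, 5.51 and 26.58 TPM. Except for Lpl in nontumour 1, these genes thus lay above DEN WT in nontumour LKO liver too, so their rise was not confined to tumour. The largest falls were in A1bg (-7.47 ± 0.99, adjusted p = 0.00402), Sult2a1 (-6.75 ± 0.94, adjusted p = 0.00539), and Sult2a2 (-6.16 ± 0.80, adjusted p = 0.00402). Next came Sult2a4 (-5.41 ± 1.00, adjusted p = 0.0193), Cyp3a44 (-5.24 ± 0.95, adjusted p = 0.0188) and Cyp2b13 (-5.21 ± 0.85, adjusted p = 0.01). In all 12 the libraries of the groups were wholly apart. Insyn1, A1bg, Sult2a1 and Sult2a2 passed whichever single library was left out. Of the 12, 8 did not pass without tumour 3, Ube2c and Nupr1 among them, 6 without tumour 2, DEN WT 3 or DEN WT 6, 3 without DEN WT 5 and 1 without DEN WT 2. With the replicate number as a block 0 of the 12 passed in limma (adjusted p = 0.473 for each), in a fit with 2 residual degrees of freedom. The blocked fold changes stayed near those above, 4.11 ± 0.62 for Insyn1, 2.89 ± 0.50 for Lpl, -7.10 ± 0.94 for A1bg and -4.46 ± 0.93 for Cyp3a44. With a term for XX or XY, chosen after seeing the data, 0 of the 12 passed either, and their fold changes were smaller in size, 2.43 ± 0.52 for Insyn1, 1.32 ± 0.40 for Lpl, 1.55 ± 0.49 for Fkbp11 and -5.56 ± 1.08 for A1bg. In a fit of the compared groups alone 9 of the 12 did not pass, at the same fold changes with 7 residual degrees of freedom, and 6 did not with no filter on low values. Slc16a1 was also lost with median-ratio scaling (2.50 ± 0.68, adjusted p = 0.0669). With the mitochondrial share as a covariate, chosen after seeing the data, it was lost too (2.11 ± 0.51, limma adjusted p = 0.0539). The fold change of Nupr1 was 1.875 ± 0.442 without tumour 3.

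Sds (-2.81 ± 0.48, limma adjusted p = 0.014) and Hal (-2.80 ± 0.49, adjusted p = 0.0156), enzymes of amino acid breakdown in periportal hepatocytes, fell. Hal had 20.95 ± 15.87 TPM in tumour against 133.64 ± 51.48 (SD, n = 3 and 6). The 4 genes of histidine breakdown had a relative median of -2.38 (camera adjusted p = 2.59e-07, and adjusted p = 0.107 with an estimated correlation), all 4 lower adjusted over the list alone, with Uroc1 and Amdhd1 at -1.89 and -1.72 beside Ftcd at -4.17. Xenobiotic metabolism genes (-1.28, camera adjusted p = 5.53e-12, and adjusted p = 0.562 with an estimated correlation) had 4 members that fell. Hepatocyte identity genes (-0.91, adjusted p = 9.43e-08, and adjusted p = 0.562 with an estimated correlation) had 1, Hpd (-2.24, adjusted p = 0.0452), an enzyme of tyrosine breakdown. The relative median was -0.58 without tumour 1. Mitochondrially encoded genes lay higher (1.01, adjusted p = 0.0115, and adjusted p = 0.665 with an estimated correlation), at 1.55 without tumour 3 and 1.52 without DEN WT 1. They were not called without DEN WT 3 or 6, with median-ratio scaling (adjusted p = 0.128) or with the replicate number as a block (0.47, adjusted p = 0.418), and camera's direction turned without tumour 1 (0.31). With the mitochondrial share as a covariate, chosen after seeing the data, hepatocyte identity genes gave -0.51 and xenobiotic metabolism genes -0.78, both called. B and plasma cell genes lay lower (-1.34, adjusted p = 1.08e-05, and adjusted p = 0.562 with an estimated correlation; -0.82 without DEN WT 5 and -0.87 with the block). NRF2 targets lay higher (0.84, adjusted p = 8.5e-05, and adjusted p = 0.576 with an estimated correlation), with 5 members adjusted over the list alone, among them the glutathione transferases Gstm3 (2.83, adjusted p = 0.0537) and Gsta1 (4.33). Fetal liver and cancer markers gave 0.67 (adjusted p = 0.00447, and adjusted p = 0.665 with an estimated correlation) and 0.20 without tumour 2 (adjusted p = 0.19). With the sex term, chosen after seeing the data, NRF2 targets were at 0.11 (adjusted p = 0.421) and fetal markers at 0.057 (adjusted p = 0.967). Scd2 (2.56 ± 0.77, adjusted p = 0.162), Cidec (2.15 ± 0.78, adjusted p = 0.275) and Pparg (0.41 ± 0.53) did not pass. Glul, glutamine synthetase, had 359.55, 6.82 and 110.19 TPM in the 3 tumours.

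Between LKO tumour and the libraries labelled WT 69 genes passed in limma, 36 higher and 33 lower, with 1461 at an unadjusted p under 0.05, and groups did not overlap in 3.2% of genes (chance 2.38%). The female-biased list (relative median -3.52, camera adjusted p = 2.48e-28) and the proliferation list (1.01, adjusted p = 5.49e-09) had adjusted p = 0.107 and adjusted p = 0.562 with an estimated correlation. Fry gave the former an adjusted p of 0.00945. Without tumour 2 the female-biased list was at -2.34, and the proliferation list was at 1.55 without tumour 1 and 0.31 without tumour 3. With the sex term they were at -1.42 and 0.56, both called. The count was 485 without tumour 1, 183 without DEN WT 1, 37 without DEN WT 5, 33 without tumour 3, 30 without DEN WT 6, 28 without tumour 2 and 27 without DEN WT 3. With median-ratio scaling it was 313, 45.7% of them higher, and with quantile normalization 40.6% of 234 were higher against 52.2% here. The share moved the other way, to 65% of 123 genes and 76.4% of 157, after removal of mitochondrial and 5S genes or with the mitochondrial share as a covariate, both chosen after seeing the data. With the replicate number as a block, a number that the labels do not explain but whose libraries deviate together in these groups, 0 genes passed beside the 69. The blocked fit held the compared groups alone. Without the block such a fit already lost 9 of the 12 genes named above, so the fall is not due to the block alone. Without the low-Ftcd libraries labelled WT, chosen after seeing the data, 420 did, 25.7% of them higher. Fold changes against these WT libraries for tumour and for nontumour LKO liver correlated with r = 0.716 across genes, where the shared WT libraries alone gave 0.344 ± 0.291 (SD) in simulations, 11 of 100 as high. The covariance was 0.44, against 0.124 simulated. The simulations did not keep the pairing of same-numbered tumour and DEN WT libraries. Splitting the 6 WT libraries into separate sets of 3 gave a median r of 0.539 over 20 divisions (0.15 to 0.663) and a median covariance of 0.36. The 4 genes called lower in nontumour LKO liver were all called lower in tumour, a comparison that shares the WT libraries, and 0 of the 4 called higher by limma were called higher in tumour.

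The fifth comparison asks what DEN leaves behind in nontumour liver labelled WT. Marker genes of immune cells lay higher after DEN as groups, while no single gene passed. The calls of the Kupffer, T and NK, and B and plasma cell lists were lost (adjusted p = 0.471 with an estimated correlation for each). All 25 tested Kupffer cell and macrophage genes were higher in sign, such as the scavenger receptor Marco (1.81), Cd5l (1.48) and the complement receptor Vsig4 (1.24), as were all 19 T and NK cell genes and all 16 B and plasma cell genes. Fetal liver and cancer markers were higher in sign in 20 of 23, with H19, an imprinted noncoding RNA of fetal liver, at 27.18 ± 32.68 TPM against 0.18 ± 0.08 (SD, n = 6 and 3; 3.54 ± 1.18, limma adjusted p = 1). The relative medians were 0.71 for Kupffer cells (camera adjusted p = 2.94e-17), and 0.69 for fetal and cancer markers (1.48e-09). They were 0.48 for T and NK cells (2.72e-09) and 0.66 for B and plasma cells (3.44e-08). Each of the 4 had adjusted p = 0.471 with an estimated correlation. Without DEN WT 5 the medians of T and NK cells and of B and plasma cells were 0.25 and 0.26. Fatty acid synthesis genes lay lower (-0.46, camera adjusted p = 4.02e-06, and adjusted p = 0.72 with an estimated correlation). They were at -0.84 without untreated WT 2. Without the low-Ftcd libraries labelled WT, chosen after seeing the data, they were at -0.201 and T and NK cells at 0.285, both still called. In limma 0 genes passed, with 95 at an unadjusted p under 0.05, and 0 passed in these lists adjusted over the list alone. The groups did not overlap in 0.7% of genes, below the 2.38% of chance, and the count stayed at 0 whichever single library was left out.

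The sixth comparison asks the same of nontumour liver labelled LKO. Cyp2a4 rose from 0.92 ± 0.75 TPM in untreated LKO to 419.06 ± 294.69 after DEN (SD, n = 3 and 3; 7.60 ± 1.03, limma adjusted p = 0.009). It reached 167.77 TPM in the XX library and 743.4 and 346 TPM in the XY libraries. Male-biased genes lay lower as a list, Hsd3b5 having 51.53, 30.75 and 47.48 TPM before and 0.71, 29.37 and 0.11 TPM after DEN. No member passed, and the list's call was lost (adjusted p = 0.181 with an estimated correlation). Cyp4a12a had 148.04, 105.98 and 161.31 against 2, 69.17 and 2.21 TPM. S1pr3 (2.74 ± 0.46, adjusted p = 0.0324), a receptor for sphingosine 1-phosphate, Cfp (2.53 ± 0.45, adjusted p = 0.0459), the complement activator properdin, and Rad51b (2.35 ± 0.42, adjusted p = 0.0486), a DNA repair protein, rose. The Mup pseudogenes Mup-ps5 (-3.66 ± 0.54) and Mup-ps11 (-3.32 ± 0.48) fell (adjusted p = 0.009 for both). Of these 6 genes 0 passed without untreated LKO 2, 5 were lost without DEN LKO nontumour 3, 4 without DEN LKO nontumour 1 or untreated LKO 3 and 3 without DEN LKO nontumour 2 or untreated LKO 1. All but Cyp2a4 were lost in a fit of the compared groups alone, at the same fold changes with 4 residual degrees of freedom (SE 0.51 for S1pr3 and 0.76 for Mup-ps5; adjusted p = 0.323 to 0.436). With a pseudocount of 0.1, 4 were lost, at larger fold changes and SE (S1pr3 4.57 ± 0.89, adjusted p = 0.134). S1pr3 was also lost with no filter (adjusted p = 0.0646), Mup-ps5 with a mean of 5 TPM or more (0.154) and Cfp with median-ratio scaling (2.34 ± 0.47, adjusted p = 0.0727).

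As lists, male-biased genes gave -1.67 (camera adjusted p = 5.01e-25, and adjusted p = 0.181 with an estimated correlation), with 0 members past limma's threshold and 8 lower over the list alone. Female-biased genes gave 1.41 with all 28 positive (adjusted p = 1.74e-13, and adjusted p = 0.295 with an estimated correlation). Of the DEN LKO libraries 1 of 3 was XX, without which the female-biased list was at 0.45, and all 3 untreated ones were XY. With a sex term, chosen after seeing the data, that list was at 0.58, still called. Kupffer cell and macrophage genes lay higher (1.48, adjusted p = 3.54e-17, and adjusted p = 0.295 with an estimated correlation), 17 of 25 adjusted over the list alone. Examples were Aif1 (2.28; 30.76 ± 13.78 against 5.65 ± 3.53 TPM; SD, n = 3 and 3), Fcer1g (2.23) and Tyrobp (2.02), signalling proteins of myeloid cells. Fetal liver and cancer markers were positive in all 23 (1.26, adjusted p = 7.3e-10, and adjusted p = 0.435 with an estimated correlation), Tff3, a mucosal repair peptide, having 166.44 ± 185.74 against 1.06 ± 0.34 TPM. The list was at 0.82 without DEN LKO nontumour 2. Dendritic cell genes gave 1.31 (adjusted p = 6.2e-06, and adjusted p = 0.295 with an estimated correlation) and T and NK cell genes 0.57 (adjusted p = 0.000674, and adjusted p = 0.797 with an estimated correlation). The 5 red cell genes had a median of 0.00 and a mean of -0.49. Camera placed them lower (adjusted p = 0.0398, and adjusted p = 0.797 with an estimated correlation). This was lost without DEN LKO nontumour 1 (0.282) or 3 (0.375) or untreated LKO 1 (0.292). The red cell call also ended with median-ratio scaling (relative median -0.20, camera adjusted p = 0.125) and quantile normalization (0.01, 0.378). With the sex term it ended too (0.079, 0.161).

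Between DEN LKO nontumour and untreated LKO 9 genes passed in limma, 5 higher and 4 lower, with 827 at an unadjusted p under 0.05. Groups did not overlap in 12.3% of genes (chance 10%), and the median of all genes was 0.12. Beside those above, the predicted genes Gm3788 (4.86) and Gm31121 (-2.12) and the protease gene Capn8 (-2.05), chosen after their values were seen, passed. The count was 20 without DEN LKO nontumour 2, 5 without untreated LKO 3, 4 without untreated LKO 1, 3 without DEN LKO nontumour 1 or 3 and 0 without untreated LKO 2, where Cyp2a4 had adjusted p = 0.0994. With median-ratio scaling 42.1% of 19 and with quantile normalization 44.4% of 18 were higher, against 55.6% here. With a term for XX or XY, chosen after seeing the data, 189 genes passed, 169 higher and 20 lower, the 9 among them. Whether the response to DEN differs between LKO and WT is the same test as that of the genotype effects above, and 0 genes passed it.

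**Figure D4:**
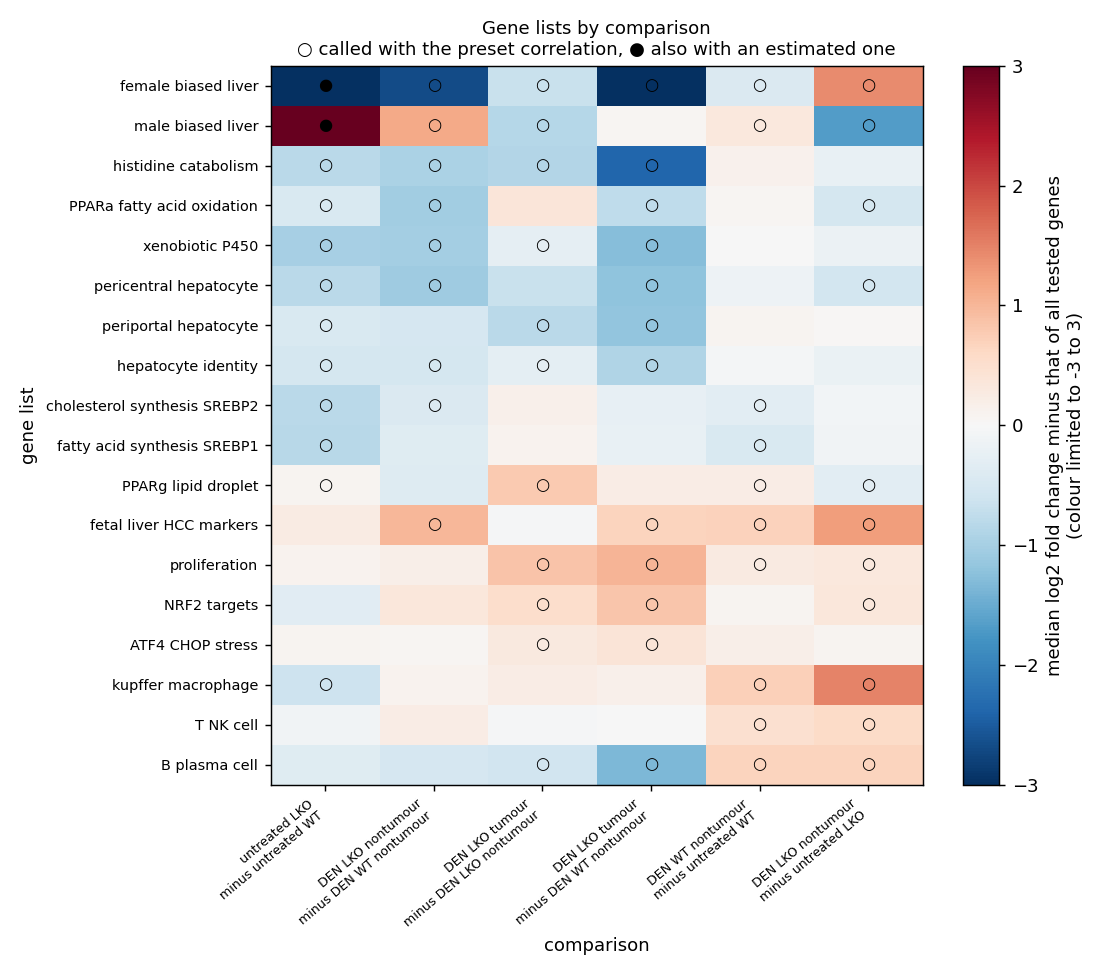
Median log2 fold change of 18 gene lists minus the median of all tested genes, by comparison (colour, limited to -3 and 3); open circles mark lists called by camera with the preset correlation and filled circles those also called with an estimated one. Among the lists drawn, the filled circles are the female-biased and male-biased lists of untreated LKO minus untreated WT, at -4.76 and 3.32.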

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

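The tests of the mitochondrial share on the genes called in untreated liver, of group differences and gene length on the first principal component, and all 3 tests on low Ftcd were chosen only after the result was seen.

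In 52 checks for a single library apart from the rest of its group, made in DEN WT, the 1 group of 6, 12 found one, while chance gives about 1 in 20 groups by the critical value used, and the checks share libraries and are not independent. DEN WT 1 held 6 of these, with 38.31% of TPM from mitochondrial genes (others 4.33 to 9.68%), 53.99% in its top 10 genes (others 22.29 to 29.65%), Xist at 48.77 TPM (others 4.97 to 14.25), Cyp2d9 at 10.37 TPM, Cyp2a4 at 128.48 TPM and Cyp2c69 at 34.22 TPM. DEN WT 2 had 66966.64 TPM of 5S ribosomal RNA, where the others had at most 5329.32. DEN WT 4 stood out with Afp at 30.43 TPM, Gpc3 at 7.44 TPM and Insyn1 at 1.45 TPM. DEN WT 5 had Hsd3b5 at 1.42 TPM and DEN WT 6 had Nupr1 at 1.14 TPM.

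By camera with the preset correlation on the difference of effects, the genotype effect differed between DEN-treated and untreated liver for 16 gene lists. It did so for 0 of them with the estimated correlation. All untreated LKO libraries were XY, while DEN LKO nontumour 1 was XX, as were all WT libraries. The difference of effects thus also holds a change in the mix of sexes. Lower after DEN were male-biased genes (-2.12), red cells (-1.30), adipocytes (-1.07), Y-linked genes (-0.996), gluconeogenesis (-0.77), PPARg lipid droplet genes (-0.67), unfolded protein chaperones (-0.52), the acute phase (-0.47) and PPARa targets (-0.45), and higher were female-biased genes (1.93), dendritic cells (0.84), fetal and cancer markers (0.67), cholangiocytes (0.62), Kupffer cells (0.58), NRF2 targets (0.53) and interferon response genes (0.47). Without DEN LKO nontumour 3 the medians were 0.40 for cholangiocytes, 0.53 for dendritic cells, 0.37 for Kupffer cells, 0.27 for NRF2 targets and -0.24 for unfolded protein chaperones, calls that this ended. Y-linked genes were at -0.12 without DEN LKO nontumour 1, acute phase genes at -0.09 without untreated WT 3, interferon response genes at 0.27 without untreated WT 1 and gluconeogenesis at -0.47 without untreated WT 2, none of them called. Others stayed called but moved, among them red cells at -2.10 without DEN LKO nontumour 2, adipocytes at -0.64 without nontumour 3, female-biased genes at 1.15 without nontumour 1, and PPARa targets at -0.78 and PPARg lipid droplet genes at -1.01 without untreated LKO 2.

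The genes called between untreated LKO and untreated WT include many that differ between male and female liver, and the 3 LKO libraries were XY and the 3 WT libraries XX. The mitochondrial share as the cause is argued against, since with it as a covariate the median size of the fold changes of the 58 called autosomal genes stayed at 0.98 of its value. Sex may account for the pattern. Of these genes 89.7% went the same way between XY and XX libraries of DEN LKO nontumour liver and 72.4% in tumour. All tested genes gave 26.9% and 21.6%. Each share rests on 1 XX library. The median differences that way, 1.17 and 0.62, were below the 3.95 of untreated liver, where the genes were selected. Loss of Ftcd is the explanation that the design names and also stays open, since 84.5% went the same way between the 1 XX LKO nontumour library and DEN WT, but 79.7% of all tested genes did so too. Sex and genotype cannot be told apart for these genes, because no untreated group holds both sexes.

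The first principal component followed the mitochondrial share of the libraries. Differences between the groups are argued against as the cause by the correlation of the deviations from group means, -0.84. Displacement of other genes by mitochondrial and 5S transcripts in TPM is argued against by a correlation of -0.88 after those genes were removed and TPM rescaled, the component then holding 37% of the variance. RNA degradation acting through gene length is argued against by the rho of gene length and loadings across genes, 0.1. What sets the mitochondrial share stays open, and no biological explanation was tested.

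Ftcd was low in 3 libraries labelled WT, DEN WT 1, DEN WT 2 and untreated WT 3. An exchange of libraries with the LKO groups is argued against, as 0 of the 9 libraries labelled LKO had Ftcd at 5 TPM or more. Loss of hepatocyte RNA is argued against, since Hal, Uroc1, Amdhd1 and Alb were at 0.24 or more of the median of the WT libraries in each of the 3, while Ftcd was at most 0.041 of it. LKO liver under a WT label stays open. All 3 lay inside the range of all LKO libraries, which reaches 3.16 TPM in untreated LKO. DEN WT 1 and 2 (2.36 and 2.5 TPM), however, lay above every DEN LKO library (0.1 to 1.75 TPM). These values are low in all these libraries and gave rise to the idea, so they do not decide it. The design names no biological explanation for low Ftcd in WT liver, and none was tested.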

How the results depend on the processing

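The sex term, the mitochondrial covariate, the removal of mitochondrial and 5S genes and the removal of the low-Ftcd WT libraries were chosen after seeing the data. Comparison 1 is untreated LKO minus WT (60 genes called), 2 is DEN LKO nontumour minus DEN WT (8), 3 is LKO tumour minus nontumour (0) and 4 is LKO tumour minus DEN WT (69). Comparison 5 is DEN WT minus untreated WT (0), 6 is DEN LKO minus untreated LKO (9) and 7 is the difference of the genotype effects (0). Leaving out 1 library gave 33 to 44 genes in comparison 1, 0 to 202 in 2, 0 to 21 in 3 and 27 to 485 in 4. It gave 0 to 0 in 5, 0 to 20 in 6 and 0 to 10 in 7. The cause of the following changes in counts by over 1.5 times was not tested. A pseudocount of 0.1 gave 2 in comparison 2 and 2 in 6. No filter gave 21 in comparison 2, 11 in 3 and 2 in 7. A mean of 5 TPM or more gave 38 in comparison 1, 3 in 2, 44 in 4 and 3 in 6, with fewer genes tested. Median-ratio scaling gave 96 in comparison 1, 1 in 3, 313 in 4, 19 in 6 and 4 in 7. Quantile normalization gave 14 in comparison 2, 1 in 3, 234 in 4, 18 in 6 and 4 in 7. Fits of the compared groups alone gave 0 in comparison 2, 3 in 4 and 1 in 7, with fewer libraries. Array weights gave 2115, 3734, 3871, 6656, 186, 1505 and 796 in comparisons 1 to 7. Their estimation stopped before convergence with weights from 0.18 to 29.11, so these counts are not used. The sex term gave 26 in comparison 1, 4 in 2, 9 in 4, 189 in 6 and 1 in 7. The mitochondrial covariate gave 0 in comparison 2, 157 in 4 and 1 in 7. TPM without mitochondrial and 5S genes gave 123 in comparison 4 and 1 in 7. Leaving out the low-Ftcd WT libraries gave 1159 in comparison 2, 420 in 4 and 2 in 7. The replicate block gave 10 in comparison 1, 0 in 2, 0 in 4, 3 in 6 and 1 in 7, with 4 of 12 named genes not passing in 1, 4 of 4 in 2, 12 of 12 in 4 and 5 of 6 in 6, and left the counts of 3 and 5 within 1.5 times. These blocked fits held the compared groups alone, so their losses need not come from the block alone. By the labels, libraries of different groups are known to share only a number, those of LKO tumour and DEN WT included. Same-numbered LKO nontumour and tumour libraries were of the same sex, with 2 of 3 correlating best with their own number and correlations of 0.35, 0.30 and -0.03, and in 0 pairs of groups did every library correlate best with its own number. Under the block 15 of 139 list calls were lost, among them cholesterol synthesis in comparison 2, bile acid genes in 3, ATF4 targets, TNF targets, Y-linked and mitochondrial genes in 4, extracellular matrix and acute phase genes in 5, red cell genes in 6 and unfolded protein genes in 2 and 7. Array weights turned the direction of Eif2s3y in comparison 3 (1.25) and of Pparg (-0.80), Srebf2 (-0.56) and Plin4 (-0.88) in 4. List directions are those of camera, given with relative medians, which can keep their sign. The sex term turned pericentral genes in comparison 1 (0.20), beta-catenin targets (-0.011) and fetal and cancer markers (-0.064) in 2, and beta-catenin targets (-0.085), TNF targets (0.048) and Y-linked genes (0.088) in 4. The mitochondrial covariate turned the mitochondrially encoded genes in comparisons 1 (-0.031), 2 (-0.21) and 4 (-0.36), which its construction removes, and acute phase (0.093) and unfolded protein genes (0.22) in 2. With 1 library left out, female-biased genes in comparison 3 lay between -1.46 and 0.11, turned without DEN LKO nontumour 1, and red cell genes between -1.07 and 0.073, turned without nontumour 2. Mitochondrial genes in comparison 4 lay between 0.31 and 1.55, turned without tumour 1, and acute phase genes in 5 between -0.021 and 0.74, turned without untreated WT 3. The estimated correlation kept 3 of 139 list calls and lost 136, and leaving out 1 library kept 961, lost 190 and turned 4. Of 644 results for named genes, 641 were the same without the variance trend, 622 with quantile normalization and 587 with the sex term. A fold threshold of log2 1 and the fit without trend left all 7 counts within 1.5 times. Depth is unknown from TPM, so which differences in genes of low TPM were detectable is unknown.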

Other observations

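Of the tests in this part, the one of the XX mouse was chosen only after the result was seen. Several gene groups not described above moved with the groups of libraries. In LKO tumours against DEN WT, acute phase genes lay lower as a list (relative median -1.10, camera adjusted p = 1.6e-06, and adjusted p = 0.562 with an estimated correlation), as did the urea cycle (-0.96, camera adjusted p = 5.11e-05, and adjusted p = 0.562 with an estimated correlation). Of the urea cycle genes, Ass1 (-2.39) and Asl (-1.36), the enzymes that make and split argininosuccinate, were lower when adjusted over the list alone, with 0.00838 and 0.02, but not over all genes. Stellate cell and fibroblast genes lay lower too (-0.54, adjusted p = 0.000302, and adjusted p = 0.562 with an estimated correlation). The adipocyte list had Fabp4 (3.02) and Cidec (2.15) higher and Pck1 (-1.80) lower over the list alone, with 0.0216, 0.0364 and 0.0265. The list as a whole was not called (camera adjusted p = 0.244). In untreated LKO, interferon response genes lay below untreated WT (-0.56, camera adjusted p = 1.43e-06, and adjusted p = 0.897 with an estimated correlation; -0.91 with a sex term chosen after seeing the data). Adipocyte genes lay above (1.11, adjusted p = 1.62e-05, and adjusted p = 0.363 with an estimated correlation), where Cfd, adipsin, was at 4.31 (adjusted p = 0.13, over the list 0.00666).

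KEGG pathways were tested besides, and 0 of 312 passed in any comparison with an estimated correlation. With the preset correlation, camera called 41 pathways lower and 1 higher in DEN LKO nontumour against DEN WT, led by the peroxisome (median log2 fold change -0.89, adjusted p = 1.66e-09, and adjusted p = 0.996 with an estimated correlation) and fatty acid degradation (-1.13, adjusted p = 6.47e-06). In LKO tumour against nontumour liver, cell cycle (0.41, adjusted p = 0.0316, and adjusted p = 0.997 with an estimated correlation) and DNA replication (0.57, adjusted p = 0.0485) were the 2 called higher. In LKO tumour against DEN WT 48 were called lower, led by retinol metabolism (-0.92, adjusted p = 3.01e-11, and adjusted p = 0.993 with an estimated correlation), and 11 higher. DEN WT against untreated WT gave 39 higher, led by the immune set named asthma (0.76, adjusted p = 1.98e-19, and adjusted p = 1 with an estimated correlation), and 1 lower.

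XY libraries of DEN LKO nontumour liver carried high Cyp2a4 (743.4 and 346 TPM, against at most 1.66 TPM in untreated XY LKO liver). Of these, replicate 2 had Cyp4a12a at 69.17 TPM and Hsd3b5 at 29.37 TPM while replicate 3 had 2.21 and 0.11 TPM. Mup20, with 1799.11 to 4548.28 TPM in untreated LKO and at most 41.21 in untreated WT, went the other way in replicate 2. It had 10382.37 TPM there and 420.47 in replicate 3. Cyp7b1 had 52.07 TPM in replicate 2, inside the untreated LKO range of 30.26 to 72.33, and 10.57 in replicate 3. A hypothesis is that male-biased expression is partly lost in XY LKO liver after DEN, which the test here does not decide, as it bears on the XX mouse alone. The XX mouse as the whole source of the lower median of the male-biased list was argued against, since the relative median was -1.31 without it, when all libraries compared were XY, and -1.67 with it. Female-biased genes were at 0.45 without it and 1.41 with it, so that most of their higher median may come from that mouse. With 2 XY libraries after DEN, and no XY liver labelled WT, whether this needs loss of Ftcd was not testable.

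Other divisions of the same libraries into groups of the same sizes were also tested. With 10 divisions of 3 against 3 a share under 0.05 cannot be had. Untreated LKO minus untreated WT called 60 genes (highest other 0, with 1 of 10 as large) and DEN LKO nontumour minus untreated LKO 9 (highest other 1, with 1 of 10 as large). LKO tumour minus nontumour called 0 genes, so the divisions cannot test it, but the highest other called 109, which points to a structure of the samples. For DEN LKO nontumour minus DEN WT, chance cannot be excluded, as 5 of 84 divisions called 8 genes or more. The highest of them called 3066 with DEN WT 3, 5 and 6 against the other 6 libraries, which points to a structure of the samples within DEN WT. For LKO tumour minus DEN WT, 4 of 84 divisions called 69 or more, a share of 0.0476, so that chance can be excluded at 0.05 only if the libraries are taken as unpaired. The highest other called 5708 with tumour 1, DEN WT 1 and DEN WT 2 together, which points to a structure of the samples. Of the 8 divisions that part the 3 pairs of same-numbered libraries, as the real one does, the highest other called 5 genes, but 8 are too few for a share under 0.05, and the 3 others with 69 or more all part 1 pair. DEN WT minus untreated WT (highest other 2436 among 84 divisions) and the difference of the genotype effects (highest other 4827 among 100 drawn) called 0 genes too, so that every division is as large and nothing is tested, while these highest counts also point to sample structure.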
